A study of Homo sapiens with 6 samples.

How the data were processed

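Gene expression was measured on Illumina HumanRef-8 v2 BeadChips, which read each transcript with one or a few short probes. Per the labels, undiluted whole blood of 2 healthy donors was kept for 3 h with 2000 IU/ml interferon beta (IFN-beta), an antiviral cytokine, or without it. Per the labels' protocols, B cells and monocytes were then taken from the blood with magnetic beads carrying antibodies against CD19 and CD14, total RNA was extracted with TRIZOL, and a single round of in vitro transcription gave the biotinylated cRNA that was hybridised. B cells came from both donors and monocytes from donor 1 alone, so the 6 arrays form 4 groups: treated B cells (n = 2), untreated B cells (n = 2), treated monocytes (n = 1) and untreated monocytes (n = 1).

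The authors deposited a table of probe intensity values on a linear scale, with no normalization visible in the values and no background subtracted, made with BeadStudio per the labels' list of processing tools. The version of BeadStudio was not given in the sources used here. Beside each intensity the authors deposited a detection p-value, which is the share of negative control probes brighter than the probe and which moved in steps of 1 in 708. The authors also deposited a processed table of intensity values. Judged from the values alone, since no source records the step, these were linear signals that had been quantile normalized within each treated and untreated pair of arrays and not across pairs. Their medians were 52.5 and 52.5 in the B cells of donor 1, 51.7 and 51.7 in monocytes, and 63.2 and 63.3 in the B cells of donor 2. Each column had a rank correlation of 1 with the unprocessed column of the same sample, which settled its direction. The linear scale was judged from the size of the values, and no centring was seen.

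The unprocessed intensities of the 6 arrays were background corrected, quantile normalized together and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the detection p-values in place of negative control probes. Tables were read with data.table (version 1.17.8), and plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Of the 22184 probes, 19715 had 1 gene symbol in the platform annotation, 0 had several and 2469 had none. The gene names of 19695 probes matched a current entry of the human gene reference (assembly GRCh38.p14), which was used for names only. XIST and Y-linked genes were removed before any step. A probe was kept if its detection p-value was under 0.01 on at least 1 of the 6 arrays, which left 12597 probes of 10291 genes. For a gene with several probes, the one with the highest mean over the 6 arrays stood for it. Of 968 genes with several probes, 41 had probes whose changes were more than 1 log2 unit apart in B cells, and 0 had one probe 2-fold up and another 2-fold down there.

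Array depth is given as the number of probes with a detection p-value under 0.01, which ran from 9394 to 10710 per array. The small number of arrays limits the precision. Where a probe was not detected on any array of a group, the comparison has only a bound. It is written "at least N-fold", from the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest detected signal and the probe's own signal. The difference of the cell types' changes is given where every group detected the probe, as a bound where only 1 group of 1 cell type did not, and otherwise without a size.

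Groups were compared with limma (lmFit and eBayes) on log2 values, fitted over all 6 arrays with 4 group means, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 2 residual degrees of freedom came from the 4 B cell arrays, so any comparison with monocytes assumed that monocyte arrays vary as B cell arrays do. The monocyte response had 1 array per condition, so it is given as sizes without a test. The replicate numbers in the labels are the donors, so they pair the samples. Over the 12597 probes, the deviations of treated and untreated B cells of the same donor from their group means had a correlation of 0.869. The same model with donor as a block has 1 residual degree of freedom, and its value is printed beside results it changed.

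Gene lists were tested with camera of limma, with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of each comparison. In monocytes a list's median was ranked among 10000 random lists of the same size matched on mean expression, and lists at or beyond the percentiles 2.5 and 97.5 were counted. The 21 lists were antiviral effectors, interferon signalling, nucleic acid sensing, chemokines, chemokine receptors, MHC class I and antigen processing, MHC class II, apoptosis, B cell activation and survival, inflammatory cytokines and NF-kB feedback, immediate early genes, heat shock and housekeeping, and markers of B cells, monocytes, T cells, NK cells, neutrophils, erythroid cells, platelets and plasmacytoid dendritic cells. They held 306 genes, of which 261 were measured. STAT1, STAT2, CD19 and IGHM were among those without a measured named probe.

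The lists, the comparisons and the rule for named genes were fixed before the data were examined. The rule took, for B cells, the 20 largest rises and 8 largest falls among genes past the threshold that moved the same way in both donors, for monocytes the 20 largest rises and 8 largest falls among detected probes, and for the cell type difference the 12 largest in each direction past the threshold. Where none passed, it took the 5 with the smallest p, said not to pass. Members of the lists served as examples. The same rule was applied after the data were seen to the fit with donor as a block, for falls in B cells and for the cell type difference.

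The steps were tested on simulated arrays in which 200 of 12597 probes were changed. For the simulated B cell response the fit without the block recovered 0% of the probes changed by 1 log2 unit, 43.3% of those changed by 2 and 90.9% of those changed by 4, with 0 false among 89 calls. The fit with the block recovered 100% at each size, with 14 false among 214 calls. The simulated spread was taken from that same fit, and a donor's shift was the same with and without treatment, as the block assumes. Its recovery is therefore a best case. For a simulated cell type difference of 4 log2 units the fit without the block recovered 0% and the fit with it 100%, with 26 false among 199 calls. Simulated monocytes were given the spread of B cells, so these counts are a best case too. Of 20 unchanged lists of 30 genes among 10291 genes camera called 0. The simulated genes varied independently of each other, so this could not test the preset correlation. In the real arrays, without the block, the estimated correlation was 0.167 for antiviral effectors, 0.801 for monocyte markers and 0.0196 for interferon signalling. It was below the preset for the other lists called in B cells, such as chemokines (-0.0384), whose camera p still rose from 0.000276 to 0.0599. A simulated list raised by 1 log2 unit had an adjusted p of 5.73e-56 with the preset correlation and 0.0629 with an estimated one, although its genes varied independently. A call lost with an estimated correlation therefore does not by itself show correlation between genes.

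The alternatives tried were no background correction, median scaling in place of quantile normalization, an offset of 50, the authors' processed values, detection on at least 2 arrays, no filter, a trended and robust variance (trended only for lists), one probe per gene, separate normalization of the cell types, donor as a block, each B cell array left out in turn, other fold sizes and the estimated correlation. Combinations of the block with other settings, and the removal of probes at least 4-fold higher in untreated monocytes than in untreated B cells, were added after the data were seen. Probes without a gene symbol entered the tests and the counts of probes but are not named.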

Results

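Transcripts were profiled in primary human B cells and monocytes isolated from whole blood that had been exposed to 2000 IU/ml IFN-beta for 3 h or left untreated. B cells of 2 donors and monocytes of 1 donor gave 6 arrays. Treated B cells had 9559 and 10105 detected probes and untreated B cells 10530 and 10710. The treated monocyte array had 9394 and the untreated one 9947. Across probes, the log2 signals of treated and untreated B cells of the same donor had correlations of 0.948 and 0.954, the pair of monocyte arrays 0.926, and B cell against monocyte arrays 0.651 to 0.780.

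The series title asks which transcripts IFN-beta induces in a cell type-specific way, and the first comparison gives the response of B cells. The largest rise was in CXCL10, a chemokine that attracts activated T cells, which rose 171-fold (log2 change 7.42, SE 0.42, n = 2 donors; limma adjusted p = 0.0283, and 7.99e-06 with donor as a block). Antiviral effectors followed. IFIT3 rose 114-fold (log2 6.83, SE 0.29), IFIT1 112-fold (log2 6.81, SE 0.24) and RSAD2, which encodes viperin, 90.3-fold (log2 6.50, SE 0.30). OASL was undetected in untreated B cells and rose at least 58.0-fold. GBP1, a guanylate-binding GTPase, rose 56.2-fold (log2 5.81, SE 0.33) and the lysosomal membrane protein gene LAMP3 61.3-fold (log2 5.94, SE 0.23), with LAMP3 and RSAD2 each detected in 1 of 2 untreated arrays.

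Further rises on the log2 scale were 5.40 for HAPLN3 (detected in 1 of 2 untreated arrays; adjusted p = 0.0491), 5.33 for OAS3, 5.23 for IFIT2, 4.61 for TNFSF10 (the death ligand TRAIL), 4.54 for EHD4, 4.47 for NEXN, 4.46 for LMO2 and 4.45 for the ISG15 ligase HERC5. RIN2 was undetected in untreated B cells and rose at least 17.4-fold. FBXO6 rose by 4.22, IFI44L by 4.18, IFI44 by 4.12 and MNDA, a gene on the fixed list of monocyte markers, by 3.96. In all, 48 probes of 12597 rose, which stood for 44 named genes by any probe and 42 by the probe used per gene, and 2 had no gene name. The count of probes that fell was 0 by limma, with 1177 probes in either direction at an unadjusted p under 0.05. The fit with donor as a block had 1109 probes higher and 1380 lower, and the 48 were among them.

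Of the 46 antiviral effectors measured, 13 rose over all probes tested, 43 passed when adjusted over the list alone and 44 rose with donor as a block, while 42 were at least 2-fold higher in both donors. Their median log2 change was 3.15 (camera adjusted p = 1.09e-58; adjusted p = 0.25 with an estimated correlation). IFI27 (undetected in B cells) and SP100 (log2 0.41) were the 2 members that did not pass with donor as a block. ISG15, which encodes a ubiquitin-like modifier, had a log2 change of 5.08 (adjusted p = 0.0757, and 3.65e-05 with donor as a block).

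Among nucleic acid sensing genes, 2 of 15 rose, the RNA sensor RIGI (log2 3.65) and the endosomal RNA receptor TLR7 (log2 3.13). Adjusted over the list alone 8 passed, and with donor as a block 10 rose and 1 fell. The median was 1.21 (camera adjusted p = 1.73e-08; adjusted p = 0.25 with an estimated correlation). Of 18 interferon signalling genes 0 passed by limma over all probes, 6 passed adjusted over the list alone, and 9 rose and 1 fell with donor as a block. The transcription factor IRF7 had a log2 change of 3.43 (adjusted p = 0.0000346 with donor as a block) and the kinase JAK2 1.90 (0.000462). The list's median was 0.54, or 0.34 with undetected genes at their bound (camera adjusted p = 0.000879; adjusted p = 0.252 with an estimated correlation).

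Of 16 chemokines 1 rose, CXCL10, with 4 adjusted over the list alone, and 8 rose and 1 fell with donor as a block (median 0.65; camera adjusted p = 0.000879; adjusted p = 0.251 with an estimated correlation). CCL8, an attractant of monocytes, was undetected in untreated B cells and at least 29.4-fold higher after treatment (adjusted p = 0.113, and 0.00034 with donor as a block). Of 15 apoptosis genes 1 rose, TNFSF10, with 5 adjusted over the list alone and 8 with donor as a block (median 0.52; camera adjusted p = 9.83e-06; adjusted p = 0.25 with an estimated correlation). The inflammatory protease gene CASP1 had a log2 change of 2.39 (adjusted p = 0.000138 with donor as a block). Of 15 inflammatory cytokine and NF-kB feedback genes 0 passed by limma over all probes, 3 adjusted over the list alone, and with donor as a block 6 rose and 1 fell (median 0.37; camera adjusted p = 0.00652; adjusted p = 0.252 with an estimated correlation). IL1RN, the interleukin 1 receptor antagonist, had a log2 change of 4.29 (adjusted p = 0.163, and 0.000745 with donor as a block).

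Of 14 MHC class I and antigen processing genes 0 passed over all probes, 2 adjusted over the list alone and 5 with donor as a block, namely TAP1 (log2 1.65), TAP2 (1.65), PSMB8 (1.48), NLRC5 (1.13) and PSME2 (0.69). The chain genes HLA-B (0.05) and B2M (0.12) did not pass. The list's median was 0.36 (camera adjusted p = 0.000879; adjusted p = 0.251 with an estimated correlation). Of 16 B cell activation and survival genes 1 rose, TNFSF13B (log2 3.86; adjusted p = 0.0453), which encodes the B cell survival factor BAFF. In that list 6 passed adjusted over the list alone, 5 rose and 3 fell with donor as a block, and the median was 0.10 (camera adjusted p = 0.0259; adjusted p = 0.295 with an estimated correlation, and 0.142 with donor as a block). That list's call was also lost without treated donor 1 (adjusted p = 0.172) and without untreated donor 2 (adjusted p = 0.121).

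Lists that camera did not call were MHC class II (10 genes, median -0.25, adjusted p = 0.193), chemokine receptors (8 genes, 0.34, or 0.18 with undetected genes at their bound, adjusted p = 0.423), immediate early genes (17 genes, -0.40, adjusted p = 0.169), heat shock (9 genes, -0.24, adjusted p = 0.423) and housekeeping (10 genes, -0.18, adjusted p = 0.259). Without untreated donor 1 the heat shock (adjusted p = 0.00885) and immediate early lists (adjusted p = 0.0175) were called lower, while without untreated donor 2 their medians were 0.34 (adjusted p = 0.296) and 0.02 (adjusted p = 0.558), so their direction depended on the control left out. MHC class II was called lower with no filter on dim probes (adjusted p = 0.0496). With donor as a block single members passed in MHC class II (3 lower), chemokine receptors (4 higher and 2 lower), immediate early genes (1 higher and 4 lower) and housekeeping (1 lower). Without the block 0 passed in each.

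In the main setting, in which the 5 genes below were ranked, no fall passed without the block. In alternatives that were also fixed beforehand some falls did pass. Without background correction 4 falls passed, KLHL14 (adjusted p = 0.0334), ZBTB16 (0.0463), LFNG (0.0491) and MIDEAS (0.0491), and with an offset of 50 KLHL14 alone (0.0499). The 5 named genes with the smallest p among those lower in treated B cells, none of which passed, were KLHL14 (log2 -2.71; adjusted p = 0.055, and 0.000105 with donor as a block), ZBTB16 (-2.37; 0.0615 and 0.000157), LFNG (-2.60; 0.0812 and 0.000296), MIDEAS (-1.98; 0.0891 and 0.000272) and SH2D3C (-2.01; 0.0944 and 0.000336). In the fit with donor as a block the 8 largest falls, a choice made after the data were seen, were in KLHL14, LFNG, a glycosyltransferase that modifies Notch receptors, RIPOR1 (-2.56), KCNG1 (-2.48), ITPKB (-2.47), FAM43A (-2.43), ZBTB16 and BMF (-2.31), which encodes a pro-apoptotic BCL2 family protein. BMF was detected in 1 of 2 treated arrays.

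Monocyte markers were higher in treated than in untreated B cells, beside each of the groups above. Of 13, MNDA rose, 9 rose with donor as a block, and the median log2 change was 1.15 (camera adjusted p = 7.63e-05; adjusted p = 0.526 with an estimated correlation). Without treated donor 1 that median was 0.20 (adjusted p = 0.14). B cell markers had a median of -0.29 (12 genes; camera adjusted p = 0.154, and 0.0206, lower, with donor as a block; adjusted p = 0.63 with the block and an estimated correlation, and 0.00662, lower, with the authors' processed values). Medians were -0.38 for 5 T cell markers (adjusted p = 0.187), 0.26 for 6 NK cell markers (0.285), 0.02 for 8 neutrophil markers (0.518), -0.14 for 2 erythroid markers (0.965), 0.16 for 2 platelet markers (0.547) and 0.44 for 4 plasmacytoid dendritic cell markers (0.136). The erythroid median split by donor, from 12.9 to 13.8 on the B cell and monocyte arrays of donor 1 against 7.32 and 7.47 on the B cell arrays of donor 2. Over the alternatives the genes named as higher in B cells kept their direction but not their calls. Log2 changes ran from 6.35 to 6.94 for IFIT1 and from 4.37 to 4.53 for HERC5. Ranges were wider for CXCL10 (6.44 to 7.93), HAPLN3 (4.30 to 5.93), OASL (4.89 to 6.31) and RIN2 (3.28 to 4.57). The bounds given for OASL and RIN2 therefore hold for the main setting only. No probe passed without any 1 of the 4 B cell arrays, where the smallest adjusted p was 0.1 without treated donor 1, 0.226 without untreated donor 1, 0.0716 without treated donor 2 and 0.228 without untreated donor 2. The 48 became 0 with the authors' processed values (smallest adjusted p = 0.0993), in which the donors' scales differed. The fit without the block counts that as spread, and with the block 2929 passed, the 48 among them. The count was also 0 (smallest adjusted p = 0.0611) once probes at least 4-fold higher in untreated monocytes were removed before the adjustment. That took out 21 of the 48, among them CXCL10, IFIT3, IFIT1 and RSAD2. The adjustment then had fewer small p-values, so the 0 does not trace the other 27 to monocyte RNA. Other counts were 12 without a filter on dim probes, 17 with median scaling and 76 (72 higher and 4 lower) without background correction.

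**Figure D1:**
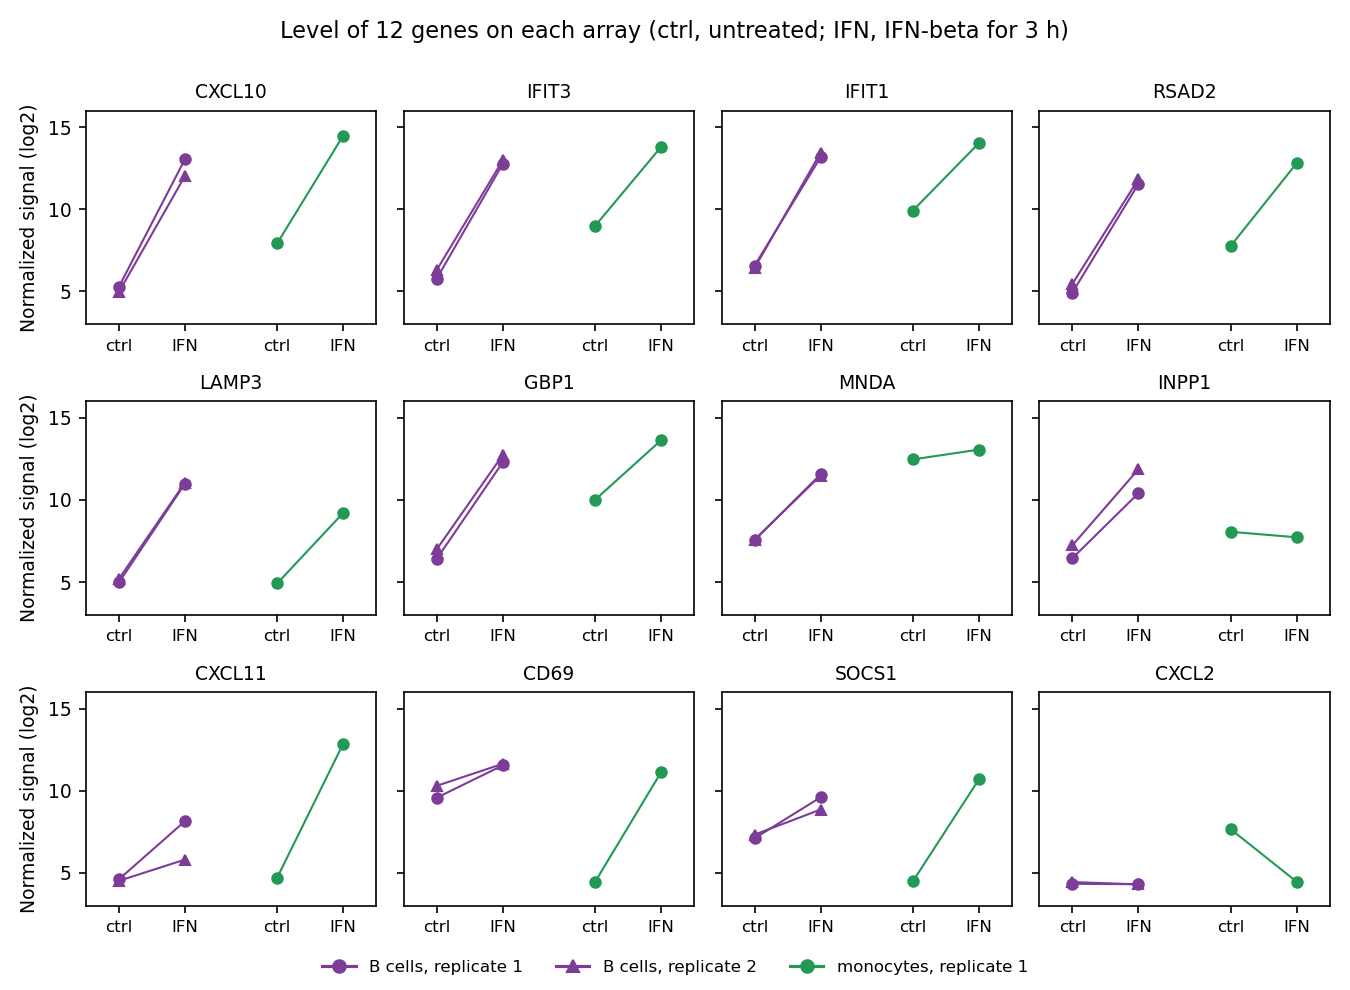
Normalized log2 signal of 12 genes, one panel each, on the 6 arrays (ctrl, untreated; IFN, treated), with a line joining the arrays of one donor and cell type. In B cells, CXCL10 rose by 7.42 and IFIT1 by 6.81 on the log2 scale.

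The second comparison gives the response of monocytes, with 1 array per condition and so no replicate check. The chemokine CXCL11 was undetected in the untreated array and at least 209.8-fold higher in the treated one. CCL8 was 149-fold higher (log2 7.22) and CXCL10 94.5-fold higher (log2 6.56). CD69, an early activation marker, was at least 62.6-fold higher, and SOCS1, an inhibitor of JAK kinases, at least 46.4-fold higher. CH25H, which makes 25-hydroxycholesterol, was at least 53.1-fold higher, and the tryptophan-degrading enzyme gene IDO1 at least 30.7-fold higher.

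Other genes undetected without IFN-beta were DEFB1 (at least 44.1-fold higher), ENPP2 (at least 40.1-fold), ABTB2 (at least 25.9-fold) and CCNA1 (at least 13.8-fold). Log2 differences were 5.26 for HESX1, 5.18 for ANKRD22, 5.04 for RSAD2, 4.84 for STAP1, 4.81 for IFIT3, 4.71 for the chemokine CXCL9, 4.67 for the cytokine subunit IL27, 4.51 for NEXN and 4.32 for RASGRP3. On the lower side, the cell cycle transcription factor gene E2F2 was at least 11.9-fold lower in the treated array, CITED4 at least 9.93-fold lower and the neutrophil attractant CXCL2 at least 4.86-fold lower. CXXC5 (log2 -3.60), OLFM1 (-3.20), PIK3IP1 (-3.14), SOX4 (-3.13) and the myeloid transcription factor gene CEBPA (-3.03) were also lower. Of 10390 probes detected on either monocyte array, 956 were at least 2-fold higher in the treated array and 845 at least 2-fold lower, and 80 and 4 were at least 10-fold so.

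Of 46 antiviral effectors, 43 were at least 2-fold higher in treated monocytes and 0 at least 2-fold lower (median log2 difference 2.41, or 2.37 with undetected genes at their bound; percentile 100 of the random lists). ISG20, an exonuclease gene, was higher by 3.41, and IFI6 had a difference of -0.60. Nucleic acid sensing genes (10 of 15 at least 2-fold higher, median 1.27) and interferon signalling genes (7 of 18, median 0.80) also stood at percentile 100. Apoptosis genes (6 of 15 higher and 1 lower, median 0.63) stood at percentile 99.9. B cell activation and survival genes (6 of 16 higher, median 0.24) stood at 99.2, with CD38 at 2.97 and the costimulatory ligand CD80 at 2.17. MHC class I and antigen processing genes (4 of 14 higher, median 0.23) stood at 99.3, with TAP1 5.67-fold higher. Inflammatory cytokine and NF-kB feedback genes (5 of 15 higher and 1 lower, median 0.25) stood at 98.9, with IL6 at 3.50.

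Chemokines were split, with 6 of 16 at least 2-fold higher, 4 at least 2-fold lower, a median of 0.17 and percentile 97.7. Beside CXCL11, CCL8, CXCL10 and CXCL9, the monocyte attractant CCL2 was higher (2.87). The neutrophil attractants CXCL8 (-2.82) and CXCL1 (-1.07) and the attractant CCL20 (-2.84) were lower. Chemokine receptors had a median of -0.50 (-0.24 with bounds) and percentile 1.5, with CX3CR1 at -2.98, CXCR4 at -2.61 and CCR1 at 1.20. Immediate early genes stood at percentile 85.6 (median 0.02), with ATF3 at 3.89 and IER3 at -2.78. Percentiles were 38 for MHC class II (median -0.24), 93 for heat shock (0.20) and 41.5 for housekeeping (-0.23). B cell markers had a median of -0.66 (-0.32 with bounds) and percentile 0.17, and monocyte markers -0.26 and 39.5, with CD14 at -1.61. Of 12 B cell markers 10 were detected on the untreated monocyte array and 4 on the treated one. Whether transcripts of other cells contributed to the differences between the monocyte arrays was not tested. Percentiles of the other marker lists were 69.1 for T cells (median 0.01), 84.6 for NK cells (0.12), 62.4 for neutrophils (-0.05), 10.1 for erythroid cells (-0.60), 77.5 for platelets (0.27) and 92.3 for plasmacytoid dendritic cells (0.24).

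When the B cell spread was assumed for monocytes, limma called 0 probes (smallest adjusted p = 0.105; 1399 at an unadjusted p under 0.05), and 2913 with donor as a block, 1376 of them higher. With median scaling, which set the median change of all probes at -0.18 in monocytes and not -0.07, 726 probes were at least 2-fold higher and 1184 lower.

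The third comparison asks whether the response differed between the cell types. By limma 0 probes passed (smallest adjusted p = 0.478; 682 at an unadjusted p under 0.05), and with donor as a block 1050 passed, of which 555 had a monocyte minus B cell change above 0, that is a larger rise or a smaller fall in monocytes, and 495 one below 0. Monocytes had 1 array per condition, so their spread was assumed to be that of B cells. The 5 genes with the smallest p, none of which passed without the block, were ABTB2, TRIB2 (monocyte minus B cell log2 change 3.73), SLC1A3, IDO1 and TNFSF18, each with an adjusted p of 0.00247 with donor as a block. All but TRIB2 were undetected in untreated B cells, so the size of their difference was not measured.

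With donor as a block, and chosen after the data were seen, the rule took the 12 named genes with the highest fitted difference and the 12 with the lowest. Above 0 the difference was 4.11 for IL27 (detected in 1 of 2 arrays of each B cell group), 3.73 for TRIB2, at least 4.32 for CD69 and at least 3.53 for SOCS1. CXCL11, DEFB1, which encodes an antimicrobial peptide, CH25H, ABTB2, CCNA1, ANKRD22, HESX1 and SLC1A3 were undetected in untreated B cells, so no size is given. Below 0, genes with a larger rise in B cells were INPP1 (-4.63), MNDA (-3.36), LMO2 (-3.22) and EHD4 (-3.19). INPP1, an inositol phosphatase gene, was 4.29 higher in treated B cells and had a difference of -0.33 in monocytes. CYP2J2, ERICH3 and MTCL1 also rose in B cells and were undetected in at least 1 monocyte array. SOX4 (-3.46), E2F2 (at most -2.91), CITED4, OLFM1 and CXCL2 were instead lower in treated monocytes, and the last 3 were undetected in B cells.

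Antiviral effectors changed less in monocytes than in B cells (median difference -0.90, or -0.94 over the 41 genes detected in all 4 groups; camera adjusted p = 0.000127; adjusted p = 0.905 with an estimated correlation). In the fit with donor as a block 15 of 46 were smaller in monocytes and 2 larger. Monocyte markers also differed (median -1.81, or -1.95 over the 10 detected in all 4 groups; camera adjusted p = 0.0133; adjusted p = 0.905 with an estimated correlation). That call was lost without treated donor 1 (median -0.55, adjusted p = 0.171), without untreated donor 2 (median -0.87, adjusted p = 0.0541) and with no filter on dim probes (adjusted p = 0.058).

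The remaining 19 lists were not called, with adjusted p from 0.0899 for chemokine receptors and 0.101 for B cell activation and survival to 0.953 for erythroid markers. The chemokine receptors and B cell activation lists were called with median scaling (adjusted p = 0.013 each), with the authors' processed values (0.0101 and 0.0352) and without untreated donor 2 (0.038 each). The heat shock list was called without untreated donor 1 (adjusted p = 0.0123).

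Across 10291 genes the log2 changes in B cells and monocytes had a Pearson correlation of 0.576 and a Spearman correlation of 0.497, over genes, which are not independent replicates. Between the B cells of the 2 donors the Pearson correlation was 0.849. Of 492 genes at least 2-fold higher in treated B cells and 780 in treated monocytes, 287 were shared, against 37.3 for independent lists, among them CXCL10, IFIT3, RSAD2 and NEXN. Of 322 and 737 genes at least 2-fold lower, 117 were shared, against 23.1. Monocyte transcripts were higher in treated B cells, so the shared rises and the correlation may in part reflect monocyte RNA. Its part in them was not tested. TRIB1 and UBASH3B were higher in B cells and lower in monocytes, and NSUN7, SELENOO, SLCO4A1 and TESK1 the reverse.

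**Figure D2:**
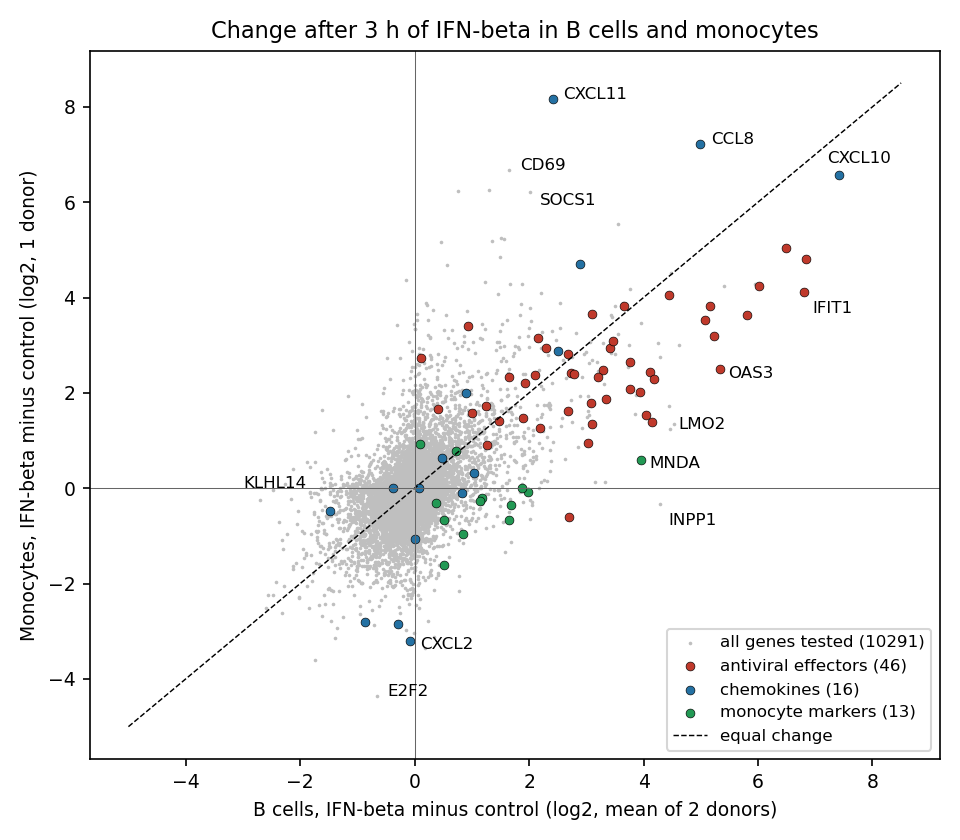
Log2 change with IFN-beta in monocytes (1 array per condition) against B cells (mean of 2 donors), one grey point per gene, with antiviral effectors, chemokines and monocyte markers coloured and a dashed line of equal change. Fitted values are plotted for undetected probes too. Changes had a Pearson correlation of 0.576 across 10291 genes.

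The untreated arrays compare the cell types themselves, with 1 monocyte array against 2 B cell arrays, so the spread of monocytes was again assumed to be that of B cells and the calls hold only under that assumption. In monocytes the S100 protein gene S100A9 was higher by 7.44 log2 units and the matrix proteoglycan gene VCAN by 7.50, and CD14, on which the beads bind, by 8.12 (detected in 1 of 2 untreated B cell arrays). The B cell receptor subunit gene CD79A differed by -5.93 and MS4A1, which encodes CD20, by -5.81. Of 13 monocyte markers 10 were higher in monocytes (median 6.96; camera adjusted p = 5.88e-10; adjusted p = 0.488 with an estimated correlation), and of 12 B cell markers 10 were lower (median -5.68; adjusted p = 6.08e-09; adjusted p = 0.262 with an estimated correlation). Of 8 neutrophil markers 6 were higher in monocytes (median 4.49, or 4.10 with undetected genes at their bound; adjusted p = 5.81e-08; adjusted p = 0.262 with an estimated correlation), among them FCGR3B (5.83). Antiviral effectors were higher too (10 of 46, with ISG20 lower; median 0.59; adjusted p = 0.00357; adjusted p = 0.588 with an estimated correlation).

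Chemokines (8 of 16 higher, median 2.72, or 2.67 with bounds; camera adjusted p = 1.49e-05), inflammatory cytokine and NF-kB feedback genes (5 of 15, median 1.23; 0.000314), apoptosis genes (4 of 15 higher and 1 lower, median 0.78; 0.00606) and immediate early genes (3 of 17 higher and 1 lower, median 0.89, or 0.79 with bounds; 0.00752) were also called higher. With an estimated correlation these had adjusted p = 0.262, 0.271, 0.34 and 0.517. The remaining 13 lists were not called. In all, 983 probes were called higher in the 1 untreated monocyte array and 600 lower (limma), and with donor as a block 2789 and 3734. The 1583 became 452 without untreated donor 1 and 446 without untreated donor 2.

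**Figure D3:**
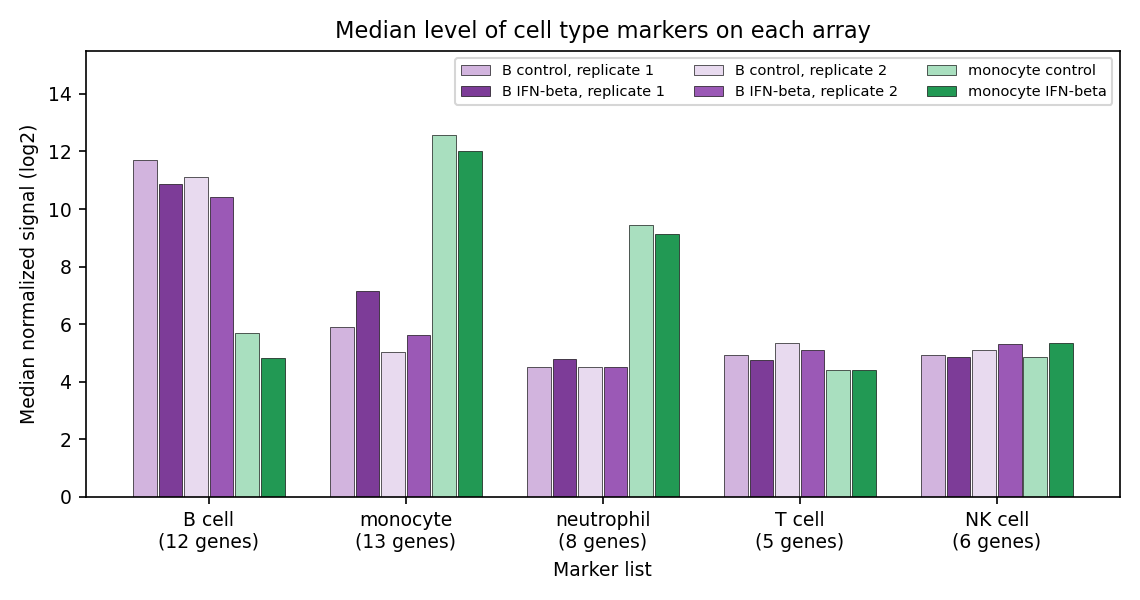
Bars give the median normalized log2 signal of the marker genes of B cells, monocytes, neutrophils, T cells and NK cells on each of the 6 arrays. Monocyte markers had a median of 12.6 in untreated monocytes, and B cell markers 11.7 and 11.1 in untreated B cells.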

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

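The tests of MNDA, of the genes called in B cells and of chemokines and cytokines were chosen after the result was seen, as were the single genes named from the fit with donor as a block and the genes with opposite changes. No group had enough arrays for a test of outlying samples.

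Monocyte transcripts were higher in treated than in untreated B cells, and the monocyte marker list was called for the cell type difference (median -1.81; camera adjusted p = 0.0133, 0.905 with an estimated correlation, and 0.171 with a median of -0.55 without treated donor 1). Abundant monocyte transcripts outside the marker list that IFN-beta left within 0.5 log2 units in monocytes had median changes of 1.94 (24 transcripts, 91.7% higher) and 0.77 (21 transcripts, 95.2% higher) in the B cells of the donors, against -0.04 for all probes in each, which fits more monocyte RNA in the treated B cell preparations, despite the CD19 beads. Their gains were at the median 2.83% and 0.384% of the treated monocyte signal, and the smaller of the donors' interquartile ranges over the median was 0.513, with 1.90 in the other donor, so that gene by gene induction cannot be told apart from it for these transcripts. Monocyte RNA as the whole source is argued against for MNDA, whose gain was at least 7.25 times the 95th percentile of those transcripts (4.55% and 4.12%) and at least 2.97 times the highest gain of any of them or of another monocyte marker (10.9%, LYZ, and 10.5%), and for the genes called higher, of which 97.6% (41 of 42, all but APOBEC3A) exceeded that percentile in both donors and 40 that highest gain (all but APOBEC3A and TNFSF13B). With donor as a block 854 of 943 genes called higher (90.6%) exceeded the percentile and 789 the highest gain. Both sets were picked by their rise in the same B cell arrays, which favours a high gain, so these counts speak for the picked genes alone. The gains of both donors were taken relative to the treated monocyte array of donor 1, which assumes that the monocytes of donor 2 were alike. A response of the B cells themselves stays open as the biological explanation.

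Chemokines and cytokines that were at least 2-fold higher in both donors' B cells were also at least 2-fold higher in treated monocytes, so monocyte RNA was weighed as their source. Of 8 such genes, 50% (CXCL10, CXCL9, IL6 and IL15RA) gained more than the 95th percentile of the unchanged monocyte transcripts in both donors, and 3 (all of these but CXCL9) more than the highest gain above. For CXCL11, CCL2, CCL8 and IL1RN all gains in donor 2 lay below the percentile, as did those of CXCL11 and CCL2 in donor 1. Monocyte RNA and expression in B cells therefore cannot be told apart for the group. Expression by B cells stays open as the biological explanation.

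Antiviral effectors changed less in monocytes than in B cells (median difference -0.90; camera adjusted p = 0.000127, and 0.905 with an estimated correlation), with a smaller change in monocytes for 33 of 46. They were higher in untreated monocytes than in untreated B cells (median 0.59, higher in 30 of 46) and at a like level after treatment (median -0.04), which restates the smaller change and gives no cause. Saturation of bright probes on the treated monocyte array stays open as the technical explanation, since 23 effectors below log2 12 there had a median difference of -0.38 with an interquartile range of -1.40 to 0.58, and the 23 at or above it -1.45. A biological difference between the cell types stays open, and 1 monocyte donor leaves its spread unknown.

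With donor as a block 1050 probes passed for the cell type difference, against 0 without it (smallest adjusted p = 0.478). The block leaves 1 residual degree of freedom, from B cells alone, and each monocyte condition had 1 array. In the simulation, which followed the model of that fit, 26 of 199 such calls were false, and the real share may be higher. The genes below are therefore candidates under that fit only. Above 0, monocyte minus B cell differences were 4.11 for IL27, 3.73 for TRIB2, at least 4.32 for CD69 and at least 3.53 for SOCS1. The size was not measured for genes undetected in untreated B cells, whose adjusted p was 0.0113 for CXCL11, 0.00247 for DEFB1, ABTB2, CCNA1 and SLC1A3, 0.00704 for CH25H, 0.0422 for ANKRD22 and 0.00304 for HESX1. Below 0, with a larger rise in B cells, differences were -4.63 for INPP1, -3.36 for MNDA, -3.22 for LMO2 and -3.19 for EHD4. CYP2J2 and ERICH3 (adjusted p = 0.00247 each) and MTCL1 (0.00537) also rose in B cells, without a measured size of the difference. Lower in treated monocytes were SOX4 (difference -3.46), E2F2 (at most -2.91), CITED4 (adjusted p = 0.00354), OLFM1 (0.00247) and CXCL2 (0.00252), the last 3 without a measured size.

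In 6 genes the change was at least 2-fold in opposite directions. NSUN7 (difference 2.92), SELENOO (3.10), SLCO4A1 (3.26) and TESK1 (2.65) were lower in treated B cells and higher in treated monocytes. TRIB1 (-2.91) and UBASH3B (-2.81) were higher in treated B cells and lower in treated monocytes. The limma adjusted p of the difference ran from 0.00304 to 0.0139 with donor as a block, and from 0.478 to 0.604 without it.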

How the results depend on the processing

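The settings that combine the block with another choice, and those without monocyte-rich probes, were chosen after the result was seen. Where a value below moved, the cause was not tested, apart from what a setting itself changes, such as fewer arrays or probes. The authors' values also left the donors on unlike scales, with medians of 52.5 and 63.2 in treated B cells. The fit without the block counts such a gap as spread. No result past its threshold was reversed. Over all lists, called or not, medians changed sign in 9 of 273 values for B cells and 32 of 273 for the difference. None of those changes was in a list called in the main setting or in the alternative. With median scaling the monocyte balance turned from 956 higher and 845 lower to 726 and 1184.

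The 48 probes called in B cells became 76 without background correction (72 higher and 4 lower), 17 with median scaling, 12 with no filter on dim probes, and 0 with the authors' processed values and without monocyte-rich probes, where the p-values were adjusted over the remaining 11660 probes. Leaving out 1 B cell array gave 0 to 0. Removing the monocyte-rich probes took out 21 of the 48, among them CXCL10, IFIT3 and IFIT1. Without the readjustment the other 27, which were not monocyte-rich, kept their calls. Their loss after readjustment therefore goes with the small p-values taken out and does not trace them to monocyte RNA. With donor as a block the count was 2489, and with the block it was 2548 without background correction, 2852 with median scaling (874 higher and 1978 lower), 2929 with the authors' values, 2087 with an offset of 50 and 2253 without monocyte-rich probes. For the cell type difference the block gave 1050 in place of 0, which 13 of 14 alternatives kept. The 1583 probes that differed between untreated cell types became 868 with median scaling, 374 with the authors' values, 6523 with the block and 446 to 1087 with 1 B cell array left out.

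The 1801 monocyte probes became 3844 at 1.5-fold, 703 at 3-fold, 1184 with an offset of 50, and 1185 with the authors' values. A count of another kind, of probes past an adjusted p of 0.05 in the fit over all 6 arrays, was 0 for monocytes. Median scaling moved the median change of all probes from -0.04 to -0.15 in B cells. Of the list counts, the 9 called in B cells became 0 with an estimated correlation and stood between 7 and 11 otherwise. The 2 called for the difference became 0 with an estimated correlation, 4 with median scaling, 4 with the authors' values, 1 with no filter and 1 to 3 with 1 array left out. With an estimated correlation a simulated raised list of independent genes did not pass either (camera adjusted p = 0.0629). Those counts of 0 therefore do not show correlation between genes. Across genes the correlation of 0.576 was 0.603 without background correction, 0.600 with an offset of 50, 0.609 with the authors' values, 0.597 for probes detected on 2 arrays and 0.491 to 0.517 with 1 array left out. Monocyte lists at or beyond the percentiles 2.5 and 97.5 numbered 7 to 10. For genes named in B cells, 277 values over the alternatives kept their side of the threshold, 15 passed it newly and 128 lost it. The losses include every setting with 1 B cell array left out, which leaves 1 array in a group and fewer residual degrees of freedom. With all arrays kept, the genes named as higher passed in 5 (HAPLN3) to 9 (IFIT1 and LAMP3) of 10 alternatives, and CXCL10 in 8. For the difference 333 kept their side and 26 passed newly. For monocytes 120 were within the tolerance and 72 moved. The tolerance was the SD of the same gene's change between the 2 B cell donors, such as 0.00506 for CEBPA and 1.69 for ANKRD22. It does not measure the spread of monocytes, so these counts do not tell how stable the monocyte values are. The block changed the calls of 2 lists in B cells, both given in the report, and of 0 lists for the difference. The arrays limit what can be said of dim probes, for which folds against an undetected group are bounds, while list medians and counts use the fitted values.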

Other observations

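The genes in this part were chosen after the result was seen. Beyond the 20 largest rises, other genes that rose in B cells by limma lay outside the fixed lists. The Notch ligand gene DLL1 rose by 3.00 log2 units (adjusted p = 0.0358), and IL2RA, the alpha chain of the interleukin 2 receptor, by 2.75 (adjusted p = 0.0495). The transcription factor gene BATF3 was undetected in untreated B cells and rose at least 6.29-fold (adjusted p = 0.0446), and the sulfotransferase gene CHST12 rose by 3.29 (adjusted p = 0.0445). CYP2J2, an arachidonic acid epoxygenase gene, rose by 3.93 (adjusted p = 0.0333) and was undetected on both monocyte arrays. The cytidine deaminase gene APOBEC3A rose by 3.50, with gains of 4.71% and 3.92% of the treated monocyte signal, which exceeded the 95th percentile of unchanged monocyte transcripts (4.55% and 4.12%) in 1 donor only. Each was higher in both donors.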
